A study of Mus musculus with 54 samples.

How the data were processed

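RNA sequencing and ATAC-seq were carried out on R1 mouse embryonic stem cells at days 0, 2, 4, 10 and 20 of differentiation in retinoic acid. Per the labels' protocols, RNA was taken with RNeasy columns, polyA RNA was selected and libraries were made with NEBNext Ultra reagents, and ATAC libraries were made with the Tn5 transposase. The labels name 22 RNA libraries (7, 3, 3, 5 and 4 by day) and 32 ATAC libraries (7, 6, 9, 4 and 6 by day), and each library was put in the group of the day its title gives. The submitters' processing notes name RSEM, without a version, and the mm9 build. Other steps, such as read trimming, the annotation and the ATAC peak caller, are not given in the sources used here.

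The authors deposited 1 expression table with a column per RNA library. Its unit was taken as FPKM from the values: library sums ranged from 472122 to 678222, which rules out TPM over the deposited genes, though TPM over a wider gene set is not excluded. The authors also deposited 1 openness signal per region and day, pooled over the ATAC libraries of a day in a way the sources used here do not describe. The 5 columns have medians near 1.22 and 1 shared maximum, so they look as if they had been brought to 1 distribution before deposit, and an increase in openness of the whole genome could not be seen in them.

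FPKM keeps no read counts, so precision at low values was judged from ratios of low values, which come from few reads. For each library the low values of genes were divided by those of the same genes in day-0 replicate 1. The most frequent ratio, allowing for ratios of whole reads, estimates what 1 read is worth relative to that replicate. It was resolved for 9 other libraries and ranged from 0.93 (day-4 replicate 1) to 1.42 (day-0 replicate 4). In day-20 replicates 1 and 2 it was 1.22 and in day-20 replicate 4 it was 1.39. For the remaining 12 libraries it was not resolved, and the estimate used was the third that was tried. Whole reads were not recovered, because a gene's effective length enters its FPKM. Totals of reads are not given in the sources used here.

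Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), as deposited, in 1 group-means model over all 22 libraries with the empirical Bayes trend, which shares 1 estimate of spread between days and leaves 17 residual degrees of freedom. Genes with 1 FPKM or more in at least 3 libraries were kept, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 per comparison, 2-sided. A log2 change on this scale understates the change of low genes. The 7 comparisons were each later day against day 0 and each consecutive step, so the 4 against day 0 share their day-0 libraries, and no overlap between them was computed. A moderated F test asked for any difference among days. A gene was specific to a day if its mean was above that of each other day at an adjusted p under 0.05 and by 2-fold.

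The 26 gene lists were fixed from textbook knowledge before the data were examined, as were the comparisons, tests, thresholds, the rule for named genes and most alternatives. Lists with 5 or more measured members were tested with cameraPR on the moderated statistics at a preset correlation of 0.01, adjusted over 26 lists and 7 comparisons, and again with camera and a correlation estimated per list. fry, which asks only whether a list's genes move on balance 1 way, was an alternative. Named genes were, in each comparison with day 0, the 6 largest changes in each direction among called genes whose libraries did not overlap and whose higher mean was 5 FPKM or more, the 4 largest in each direction for the consecutive steps, up to 4 called members of each list per comparison, 15 genes fixed by name and the 4 most abundant day-specific genes of each day. The text gives a selection of the genes that this rule names, and some others, among them 1 of those fixed by name, are not reported here. Genes in the closing section's families were named after their values were seen. Members of near-identical families, such as the Zscan4 genes, small proline-rich genes, protocadherins and gene models, may share reads with their copies, and so may MHC genes, which also vary between strains.

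Openness values had no replicates, so regions were counted and not tested: a region counted as higher or lower where openness + 0.1 differed 2-fold and reached 1 on the higher day. The 3 largest differences in each direction were the regions open to naming. Coordinates are those of the authors' mm9 table, counted from 1. No annotation of that build was used here, so regions carry no gene names, and the planned comparison of openness with expression was not run.

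The limma, list and day-specific steps were tested on simulated data before use, with 14982 genes and the real day sizes, 200 of them changed. The changed genes were drawn only from those with a day-0 mean above about 5 FPKM, so recovery of lower genes was not checked. At a 3-fold change 100% of the changed genes were called in each of the 7 comparisons. At 1.5-fold the share ran from 83% (day 4 against day 2) to 97% (day 10 against day 0). False calls made up 3.61% to 6.47% of calls, 0 unchanged lists were called, and 99.5% of simulated day-specific genes were found. Simulated genes varied independently of each other, so the check cannot show how often lists of genes that move together are called falsely. Far more genes were called in the data than the 200 changed here, so the share of false calls need not carry over. Replicate numbers in the titles run from 1 in every day, and whether they pair libraries was checked. The alternatives covered the pseudocount, the filter, the scaling, the variance model, the libraries in the model, the thresholds, the replicate number as a block and each library left out. The sets of day-0 libraries as separate baselines, the rescaling of lists to the same sum and the chromosome settings for openness were chosen after seeing the data. Chromosomes of genes came from the reference gene table by symbol. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.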

Results

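Gene expression and chromatin openness were followed in R1 mouse embryonic stem cells as they differentiated in retinoic acid, a vitamin A derivative that acts through nuclear receptors and directs embryoid bodies towards neural fates. The cells were aggregated into embryoid bodies in hanging drops for 48 h and then kept in medium to which, per the labels, 0.5 mM retinoic acid was added. RNA was sequenced from 22 libraries, 7 at day 0, 3 at day 2, 3 at day 4, 5 at day 10 and 4 at day 20. Chromatin openness was measured by ATAC-seq, which marks DNA that a transposase can reach, with 1 deposited value per region and day. The labels do not say whether day 0 was sampled before or after aggregation, or whether the libraries of a day came from separate cultures. The p-values therefore measure only the spread between libraries, which may be technical. RNA levels are the deposited FPKM, given as mean ± SD over the libraries of a day, and changes are log2 values with 1 FPKM added, ± SE from limma.

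The table held 21960 genes, of which 14982 reached 1 FPKM in at least 3 libraries and were tested, and 2251 were listed at 0 in every library. Library sums ran from 472122 to 678222 FPKM and genes above 0 from 16131 to 17948. Libraries of the same day correlated at 0.99 to 0.998 across genes, which are not independent replicates. Read counts were not used here, so depth was known only in part. The most frequent ratio of low values gave the worth of 1 read relative to day-0 replicate 1. It was 1.42 in day-0 replicate 4, 1.19 in day-4 replicate 3 and 1.39 in day-20 replicate 4, a more valuable read meaning a shallower library. The day-0 libraries fell into 2 sets, replicates 1 to 3 and replicates 4 to 7, seen in the data and accounted for by no label. Between these sets 3840 genes were called at an adjusted p under 0.05, 2360 higher and 1480 lower in replicates 4 to 7, whereas the next highest of the 35 splits of 3 against 4 called 2. Comparisons with day 0 are therefore also given against each set alone.

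Among marker genes, Pou5f1 was at its highest at day 0, Tubb3 at day 4 and Gfap at day 20. Pou5f1, which encodes the pluripotency factor OCT4, stood at 865 ± 116, 37.9 ± 3.38, 3.14 ± 0.121, 1.09 ± 0.198 and 0.195 ± 0.124 FPKM at days 0, 2, 4, 10 and 20. Over the same days Tubb3, a neuronal tubulin, stood at 31.4 ± 1.24, 9.67 ± 0.306, 688 ± 3.99, 242 ± 13.1 and 59.3 ± 4.13 FPKM. Gfap, an intermediate filament of astrocytes, stood at 0.244 ± 0.399, 0.103 ± 0.0577, 0.030 ± 0.0361, 185 ± 13.3 and 1413 ± 65.6 FPKM. A difference among the 5 days was called for 14872 of 14982 genes (limma F test). Genes whose mean was at least 2-fold above that of each other day, at an adjusted p under 0.05 in all 4 limma contrasts, numbered 622 at day 0, 117 at day 2, 268 at day 4, 229 at day 10 and 1394 at day 20. The most abundant of these were Hsp90aa1 (2948 ± 207), Dppa5a (2464 ± 81.8), Hspb1 (967 ± 38.2) and Pou5f1 at day 0. At day 2 they were Mdk (4970.0 ± 289), Crabp2 (1084 ± 23.5), Stra8 (608 ± 9.19) and Eno1b (558 ± 19.5). At day 4 they were Stmn1 (1448 ± 60.8), Tubb3, Nefm (522 ± 17.1) and Ina (461 ± 5.07), the last 2 encoding neurofilament subunits. Rtn1 (464 ± 25.2), Ptn (176 ± 5.81), Gpm6a (156 ± 12.2) and Podxl2 (149 ± 13.5) led at day 10. Clu (5483 ± 213), Apoe (4502 ± 441), Tff1 (3274 ± 342) and Sprr2a2 (2874 ± 263) led at day 20. The last belongs to a family of near-identical copies, so its value is uncertain.

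Day means correlated across genes at 0.913 between days 0 and 2, 0.895 between days 2 and 4, 0.907 between days 4 and 10, 0.878 between days 10 and 20 and 0.661 between days 0 and 20. Of 182 pairs of a gene list and a comparison, limma's camera test with its preset correlation called 104, 55 up and 49 down, and 46 of these were also called with a correlation estimated from the libraries. In 100 random regroupings of the 22 libraries the preset correlation called a median of 78 pairs and the estimated correlation a median of 0. The adjusted p with an estimated correlation is therefore given for each called list that is named, alone where both called it, and after the preset camera value where only that did. Median, mean and test of a list differed in sign in 32 of the 182 pairs, of which 2 were called with the preset correlation and 0 with the estimated one. List medians below are relative to the median change of all genes in the same comparison.

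**Figure D1:**
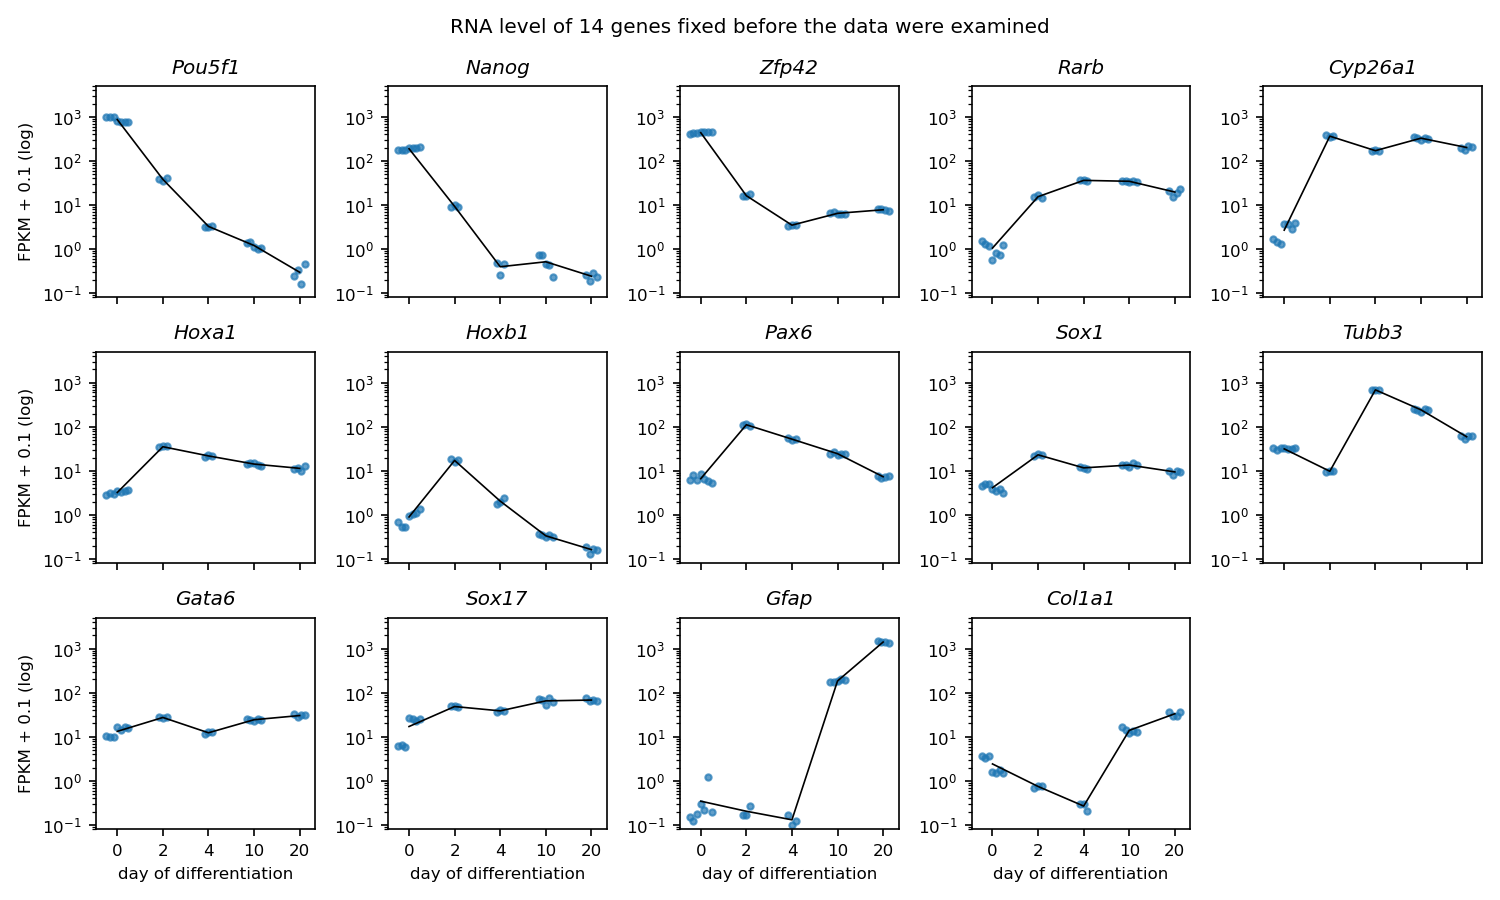
RNA level of 14 genes fixed by name before the data were examined, as FPKM with 0.1 added on a log axis against the day of differentiation, with days evenly spaced, 1 point per library and lines joining day means. Pou5f1, Nanog and Zfp42 are highest at day 0, Tubb3 peaks at day 4, and Gfap rises between days 4 and 20 from 0.030 ± 0.0361 to 1413 ± 65.6 FPKM.

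In the first 2 days pluripotency genes fell and retinoic acid targets rose. Tdgf1, a co-receptor of Nodal signalling, fell from 398 ± 53.7 to 2.11 ± 0.316 FPKM, a log2 change of -7.0 ± 0.11. Pou5f1 fell from 865 ± 116 to 37.9 ± 3.38, Nanog from 188 ± 11.5 to 9.14 ± 0.55 and Esrrb from 150.4 ± 7.93 to 2.75 ± 0.13 FPKM. Cyp26a1, whose enzyme breaks down retinoic acid, rose from 2.56 ± 1.18 to 363 ± 18.6 FPKM (6.75 ± 0.19). Its day-0 values were 1.22 to 1.59 FPKM in replicates 1 to 3 and 2.67 to 3.84 in replicates 4 to 7. Rbp4, a retinol carrier, rose from 1.81 ± 0.511 to 286 ± 6.17 FPKM and Rarb, a retinoic acid receptor, from 0.944 ± 0.35 to 15.2 ± 1.11. The cellular retinoic acid-binding protein gene Crabp2 rose from 14.2 ± 1.3 to 1084 ± 23.5 FPKM. Hox genes, which set position along the body axis, were low at day 0. Hoxb8 rose from 0.331 ± 0.137 to 105 ± 1.94 FPKM (6.32 ± 0.09), Hoxb6 from 0.109 ± 0.0267 to 53.4 ± 1.34 and Hoxb5 from 0.237 ± 0.0939 to 48.5 ± 0.913. The nuclear receptor gene Nr2f1 changed by 5.66 ± 0.07. Spry4 and Etv4, both induced by FGF signalling, changed by -5.95 ± 0.09 and -5.03 ± 0.17, and Utf1, Fgf4 and Fgfbp1 by -5.06 ± 0.10, -4.71 ± 0.06 and -5.22 ± 0.16.

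In the pluripotency list 1 of 26 measured members rose and 25 fell, with a median of -3.20 (adjusted p = 4.3e-05 with an estimated correlation). In the primed-epiblast list 2 of 14 measured members rose and 12 fell (adjusted p = 0.00345 with an estimated correlation). Sox3, a neural and epiblast factor, rose from 3.55 ± 0.406 to 82.1 ± 2.4 FPKM, whereas Otx2 fell from 20.9 ± 3.81 to 0.39 ± 0.0964. Among retinoic acid signalling genes 18 of 23 measured members rose and 3 fell (median 3.01, adjusted p = 0.00232 with an estimated correlation). Hox genes of paralogue groups 1 to 5 rose in 15 of 15 cases (median 3.88, adjusted p = 0.029 with an estimated correlation). Of groups 6 to 13, 11 of 14 measured members rose and 2 fell (camera adjusted p = 1.21e-10, adjusted p = 0.119 with an estimated correlation). In the neural progenitor list 20 of 25 measured members rose and 2 fell (adjusted p = 0.0299 with an estimated correlation). Dbx1 rose from 0.0129 ± 0.017 to 41.5 ± 2.85 FPKM, Irx3 from 0.666 ± 0.181 to 59.6 ± 2.98 and Pax6 from 6.52 ± 1.14 to 111 ± 6.14. For neurogenic transcription factors 17 of 29 measured members rose and 4 fell (camera adjusted p = 0.00112, adjusted p = 0.148 with an estimated correlation), with Neurog2 at 17.9 ± 1.13 FPKM at day 2.

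Genes of definitive and extraembryonic endoderm also rose. Of their list 26 of 28 measured members rose and 0 fell, or 27 adjusted over the list alone (median 2.65, camera adjusted p = 2.09e-14, adjusted p = 0.132 with an estimated correlation). The apolipoprotein gene Apoa2 rose from 0.060 ± 0.102 to 70.6 ± 1.65 FPKM, Apoa1 from 0.0386 ± 0.0708 to 47.7 ± 0.671 and Sox17 from 17 ± 10.2 to 48.4 ± 1.92. At day 0 Sox17 stood at 5.79 to 6.47 FPKM in replicates 1 to 3 and 23.1 to 26.3 in replicates 4 to 7, so the size of its rise depended on the set. Markers of this list differed between the sets of day-0 libraries, and its median was 2.89 against replicates 1 to 3 and 2.40 against replicates 4 to 7. In the germline list 1 of 14 measured members rose and 10 fell (adjusted p = 0.0304 with an estimated correlation). The member that rose was Stra8, named for its response to retinoic acid, from 156 ± 16.1 to 608 ± 9.19 FPKM. Of stress and immediate early genes 13 of 19 fell, or 14 adjusted over the list alone (camera adjusted p = 2.88e-06, adjusted p = 0.079 with an estimated correlation). Hspb1, a small heat shock protein, fell from 967 ± 38.2 to 153 ± 8.12 FPKM. Of DNA methylation genes 2 of 11 measured members rose and 7 fell (camera adjusted p = 0.0157, adjusted p = 0.312 with an estimated correlation). Tet1 fell from 92.1 ± 13.6 to 5.2 ± 1.16 FPKM and Dnmt3l from 219.9 ± 63.3 to 15.5 ± 1.63. In the 2-cell-like list, named for a state of the early embryo and full of near-identical copies, 9 of 12 measured members rose and 1 fell (camera adjusted p = 0.198).

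The primitive streak list held 3 members that rose and 4 that fell of 10 (camera adjusted p = 0.968). The cardiac list held 4 and 5 of 14 (camera adjusted p = 0.926) and the neural crest list 4 and 5 of 10 (camera adjusted p = 0.694). Members of the endothelium and blood list that rose and fell numbered 3 and 4 of 10, 3 and 5 adjusted over the list alone (camera adjusted p = 0.0824). In the glycolysis list 11 of 17 measured members rose and 5 fell, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.621). Its members moved far in both directions, Pfkp falling from 58.6 ± 3.06 to 8.92 ± 1.55 FPKM and Tpi1 rising from 64.7 ± 8.91 to 304 ± 14.9.

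In all, 11105 of 14982 genes were called, 6299 higher and 4806 lower at day 2 (limma, Benjamini-Hochberg adjusted p under 0.05). Of these 2999 changed at least 2-fold, 1809 up and 1190 down. The median change of all genes was 0.07, and -0.01 after quantile normalization. Of the calls 56.7% were higher, 49.9% after quantile normalization and 56.0% with each library rescaled to the same sum, and of the 2-fold calls 60.3%, 50.2% and 60.3%. Against day-0 replicates 1 to 3 alone 11152 genes were called and against replicates 4 to 7 alone 11101. Of these, 10351 and 10517 were among the 11105 with the same direction. The 32 genes named for this comparison were all called (highest adjusted p = 0.000366), and in 32 the libraries of the 2 days did not overlap, against 1.67% of genes by chance. Many named genes, here and in the later comparisons, had been picked for this lack of overlap, so the comparison with chance is no support for them. Counts adjusted over the list alone matched those over all genes in 20 of 26 lists.

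By day 4 genes of young neurons had risen and pluripotency genes had fallen further. Of the neuronal list 35 of 35 members rose and 0 fell (median 4.29, adjusted p = 0.0004 with an estimated correlation). Celf3, a neuronal RNA-binding protein, rose from 0.177 ± 0.103 to 172 ± 11.6 FPKM (7.20 ± 0.11) and Dcx, a microtubule protein of migrating neurons, from 0.104 ± 0.0812 to 133 ± 8.46. Gap43, a growth cone protein, rose from 2.2 ± 0.908 to 362 ± 5.84 FPKM and Tubb3 from 31.4 ± 1.24 to 688 ± 3.99. Sst, which encodes the peptide somatostatin, rose from 0.187 ± 0.155 to 245 ± 11.3 FPKM (7.70 ± 0.13). Fabp7, a lipid-binding protein of radial glia, rose from 0.29 ± 0.304 to 203 ± 2.68 (7.34 ± 0.13). Pou5f1 changed by -7.70 ± 0.10, Tdgf1 by -8.19 ± 0.11, Utf1 by -7.87 ± 0.10 and Nanog by -7.19 ± 0.09. Dnmt3l changed by -7.03 ± 0.17 and Zfp42, also known as Rex1, by -6.64 ± 0.05. Hoxb8 reached 323 ± 5.61 and Hoxb6 157 ± 7.1 FPKM, and Nr2f1 rose from 0.151 ± 0.0859 to 189 ± 5.64.

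Among neurogenic transcription factors 25 of 29 measured members rose and 1 fell (median 3.56, adjusted p = 0.00232 with an estimated correlation). Nhlh2 rose from 0.0829 ± 0.0373 to 97.6 ± 1.46 FPKM, Myt1 from 0.0329 ± 0.0386 to 76 ± 5.63 and Neurog2 from 0.0214 ± 0.0402 to 66.8 ± 3.05. Genes for making and moving transmitters rose in 12 of 13 cases and fell in 0 (adjusted p = 0.00525 with an estimated correlation). Slc18a3, of the acetylcholine pathway, rose from 0.186 ± 0.0513 to 75.1 ± 2.26 FPKM (6.01 ± 0.06) and Th, the tyrosine hydroxylase of dopamine synthesis, from 0.0357 ± 0.0355 to 22.1 ± 0.0929 (4.48 ± 0.08). Chat, also of the acetylcholine pathway, rose from 0.010 ± 0.0191 to 15 ± 0.743 (3.98 ± 0.14). Neuronal subunits of the BAF chromatin remodelling complex rose in 6 of 6 cases (adjusted p = 0.0337 with an estimated correlation), Actl6b from 0.0286 ± 0.0634 to 23.9 ± 1.03 FPKM. In the retinoic acid list 21 of 23 measured members rose and 2 fell (adjusted p = 0.00291 with an estimated correlation). Cyp26b1 rose from 0.327 ± 0.0945 to 90.7 ± 2.71 FPKM. In the neural progenitor list 21 of 25 measured members rose and 2 fell (adjusted p = 0.0486 with an estimated correlation), with Hes5 rising from 0.203 ± 0.108 to 89.7 ± 3.45 FPKM. All 15 Hox genes of groups 1 to 5 rose (camera adjusted p = 3.35e-28, adjusted p = 0.078 with an estimated correlation).

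All 26 members of the pluripotency list fell (median -5.25, adjusted p = 4.3e-05 with an estimated correlation). So did all 14 of the germline list (adjusted p = 0.00215 with an estimated correlation), Dazl from 74.9 ± 10.5 to 1.67 ± 0.252 FPKM. All 25 of the cell cycle list fell (median -1.59, adjusted p = 0.000504 with an estimated correlation), Cdk1 from 289.6 ± 11.1 to 74.8 ± 4.1 FPKM. The 12 genes of the 2-cell-like list all fell as well (camera adjusted p = 6.74e-05, adjusted p = 0.081 with an estimated correlation). In the mesenchyme list 5 of 24 measured members rose and 12 fell (camera adjusted p = 0.123). Tagln, a smooth muscle gene, fell from 97.7 ± 8.31 to 2.02 ± 0.84 FPKM. Endoderm genes mostly rose relative to day 0 (23 of 28 measured members rose and 4 fell, camera adjusted p = 0.0226, adjusted p = 0.485 with an estimated correlation), with Apoa2 at 33.1 ± 2.39 FPKM. The median of this list was 1.96 against day-0 replicates 1 to 3 and 0.75 against replicates 4 to 7.

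In this comparison 12367 genes were called, 7042 higher and 5325 lower, and 5423 changed at least 2-fold, 3328 up and 2095 down (limma). All genes together had a median change of 0.12, -0.05 after quantile normalization and 0.33 rescaled to the same sum. The share of calls that were higher was 56.9%, 47.5% and 66.5% in these 3 scalings, and of 2-fold calls 61.4%, 48.7% and 71.8%. Day-0 replicates 1 to 3 alone gave 12340 calls and replicates 4 to 7 alone 12327, of which 11807 and 11924 were shared with the full comparison. All 28 genes named were called (highest adjusted p = 3.81e-17), 28 of them with no overlap between libraries of the 2 days, for which many had been picked. In 26 of 26 lists the counts adjusted over the list alone were the same.

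At day 10 genes of radial glia and astrocytes had risen beside the neuronal genes. Fabp7 rose from 0.29 ± 0.304 to 1332 ± 57.8 FPKM (10.04 ± 0.11) and Gfap from 0.244 ± 0.399 to 185 ± 13.3 (7.27 ± 0.13). Sparcl1, a matrix protein secreted by astrocytes, rose from 0.13 ± 0.0935 to 367 ± 17.7 FPKM (8.35 ± 0.06). Bcan, which encodes brevican, rose from 0.576 ± 0.16 to 69.3 ± 4.07 FPKM. Gkn2, a gastric mucosa gene, rose from 0.314 ± 0.247 to 424 ± 23.3 FPKM (8.36 ± 0.11) and Tmem176b from 0.571 ± 0.308 to 235 ± 4.81 (7.26 ± 0.12). Pou5f1 changed by -8.69 ± 0.09, Utf1 by -8.08 ± 0.09, Tdgf1 by -7.61 ± 0.09 and Dnmt3l by -7.60 ± 0.15. The gene model Gm10073, which may share reads with a near-identical copy, fell from 413 ± 71.7 to 2.94 ± 0.542 FPKM.

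In the astrocyte and radial glia list 18 of 19 measured members rose and 1 fell (median 3.41, adjusted p = 0.00136 with an estimated correlation). In the oligodendrocyte list 14 of 15 measured members rose and 0 fell (median 3.33, camera adjusted p = 6.79e-06, adjusted p = 0.247 with an estimated correlation). Mbp, a myelin protein, rose from 1.19 ± 0.397 to 185 ± 12.7 FPKM and Olig1 from 0.0943 ± 0.0586 to 53.7 ± 5.72. Neuronal genes rose in all 35 cases (median 4.06, adjusted p = 0.00136 with an estimated correlation). Stmn4 rose from 0.23 ± 0.212 to 118 ± 4.42 FPKM and Snap25, part of the vesicle fusion machinery, from 0.306 ± 0.169 to 74.9 ± 1.01. Of transmitter genes 11 of 13 measured members rose and 2 fell (camera adjusted p = 0.00248, adjusted p = 0.0802 with an estimated correlation), now led by genes of inhibitory neurons. Slc32a1, a vesicular transporter gene, rose from 0.313 ± 0.114 to 28.7 ± 2.65 FPKM and the glycine transporter gene Slc6a5 from 0.0429 ± 0.0359 to 17.3 ± 0.301.

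Cell cycle genes fell in all 25 cases (median -3.23, adjusted p = 0.000231 with an estimated correlation), Cdc20 from 221 ± 8.48 to 16.9 ± 0.997 FPKM. The maintenance methylation cofactor Uhrf1 fell from 173 ± 12.5 to 9.33 ± 0.555. In the mesenchyme list 20 of 24 measured members rose and 3 fell (camera adjusted p = 0.0648), Col6a1 from 0.0843 ± 0.0127 to 28 ± 1.11 FPKM. For the endoderm list 23 of 28 measured members rose and 3 fell (camera adjusted p = 0.0624). Its median was 1.99 against day-0 replicates 1 to 3 and 1.27 against replicates 4 to 7. The immediate early genes Fos and Jun rose from 4.43 ± 1.27 to 139 ± 2.09 and from 11 ± 1.92 to 75.7 ± 6.93 FPKM. Their list held 10 members that rose, 11 adjusted over the list alone, and 8 that fell of 19 (camera adjusted p = 0.368).

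Calls numbered 13560, 8112 higher and 5448 lower at day 10, and 7063 at least 2-fold, 4575 up and 2488 down (limma). The all-gene median was 0.28, -0.06 after quantile normalization and 0.66 rescaled to the same sum. The share of calls that were higher, 59.8%, was 47.4% after quantile normalization and 71.0% after rescaling, and that of 2-fold calls 64.8%, 48.5% and 77.7%, so the split between up and down depended on the scaling. Against day-0 replicates 1 to 3 alone 13485 genes were called and against replicates 4 to 7 alone 13463, with 13089 and 13175 shared in direction. All 22 genes named were called (highest adjusted p = 1.01e-17), 22 of them with no overlap between libraries of the 2 days, for which many had been picked. In 24 of 26 lists the counts adjusted over the list alone were the same.

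At day 20 glial genes stood beside genes of gastric and squamous epithelium. Tff1, a trefoil peptide of the gastric mucosa, rose from 0.63 ± 0.979 to 3274 ± 342 FPKM (11.13 ± 0.27). Gkn2 rose from 0.314 ± 0.247 to 1514 ± 125 (10.19 ± 0.12), Gkn1 from 0.191 ± 0.159 to 905 ± 88 (9.58 ± 0.10) and Sprr2a2, of the cornified envelope, from 1.49 ± 1.23 to 2874 ± 263. Gfap rose from 0.244 ± 0.399 to 1413 ± 65.6 FPKM (10.20 ± 0.14), Fabp7 from 0.29 ± 0.304 to 962 ± 59.7 (9.57 ± 0.12) and Mbp from 1.19 ± 0.397 to 1645 ± 300.0. Aqp4, the water channel of astrocytes, rose from 0.00429 ± 0.00535 to 132 ± 9.93. At day 0 replicate 6 lay above the other 6 libraries for Gfap (1.14 FPKM), Tff1 (2.74) and Fabp7 (0.93). Pou5f1 fell to 0.195 ± 0.124 FPKM (-9.50 ± 0.09). Utf1, Tdgf1, Dnmt3l and L1td1 changed by -8.05 ± 0.10, -7.83 ± 0.10, -7.64 ± 0.16 and -6.92 ± 0.11.

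All 19 members of the astrocyte and radial glia list rose (median 4.45, adjusted p = 0.000493 with an estimated correlation). So did all 15 of the oligodendrocyte list (median 4.79, camera adjusted p = 4.82e-10, adjusted p = 0.181 with an estimated correlation). Mag, a myelin gene, rose from 0.0643 ± 0.0635 to 172 ± 42.6 FPKM. In the epithelium list 15 of 17 measured members rose and 2 fell (median 2.71, camera adjusted p = 2.33e-05, adjusted p = 0.204 with an estimated correlation). The keratin genes Krt5 and Krt19 rose from 0.116 ± 0.0608 to 181 ± 27 and from 5.24 ± 1.24 to 741 ± 62 FPKM. Endoderm genes rose in 22 and fell in 3 of 28 cases (camera adjusted p = 0.00178, adjusted p = 0.455 with an estimated correlation). Apoa1 rose from 0.0386 ± 0.0708 to 229 ± 28.9 FPKM and Hnf4a, a factor of liver and gut, from 0.627 ± 0.226 to 56.5 ± 3.27. The list's median was 2.40 against day-0 replicates 1 to 3 and 1.29 against replicates 4 to 7. In the neuronal list 33 of 35 measured members rose and 2 fell (adjusted p = 0.00782 with an estimated correlation). Syp, a synaptic vesicle protein, rose from 2.06 ± 1.04 to 86.4 ± 13.6 FPKM. For neurogenic transcription factors 15 of 29 measured members rose and 10 fell (camera adjusted p = 0.789), the median lying at 0.20 before and -0.18 after the all-gene shift. In the mesenchyme list 21 of 24 measured members rose and 2 fell (camera adjusted p = 0.0045, adjusted p = 0.132 with an estimated correlation), Col1a1 from 2.31 ± 1.02 to 33.1 ± 4.48 FPKM.

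The cell cycle list fell in all 25 members (median -3.58, adjusted p = 0.000205 with an estimated correlation), Top2a from 297 ± 10.9 to 21.7 ± 1.87 FPKM. The germline list fell in all 14 (adjusted p = 0.00228 with an estimated correlation). All 7 progenitor BAF subunits fell (camera adjusted p = 0.00384, adjusted p = 0.063 with an estimated correlation), Actl6a from 98.9 ± 4.46 to 22.4 ± 0.904 FPKM. Pluripotency genes fell in 25 of 26 cases (median -5.84, adjusted p = 4.3e-05 with an estimated correlation). In the retinoic acid list 19 of 23 measured members rose and 4 fell (camera adjusted p = 1.95e-07, adjusted p = 0.0656 with an estimated correlation). Cyp26b1, which also clears retinoic acid, rose from 0.327 ± 0.0945 to 293 ± 23.9 FPKM.

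For day 20, 13603 genes were called, 8281 higher and 5322 lower, and 7771 changed at least 2-fold, 5256 up and 2515 down (limma). The all-gene median lay at 0.38, -0.10 after quantile normalization and 0.62 rescaled to the same sum. Higher calls made up 60.9% as deposited, 46.7% and 67.2% in the same order, and 67.6%, 47.0% and 74.6% of 2-fold calls. Replicates 1 to 3 of day 0 gave 13607 calls and replicates 4 to 7 gave 13586, and 13225 and 13285 of these were shared in direction. All 23 genes named were called (highest adjusted p = 8.38e-15), 23 of them with no overlap between libraries of the 2 days, for which many had been picked. In 26 of 26 lists the counts adjusted over the list alone were the same.

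**Figure D2:**
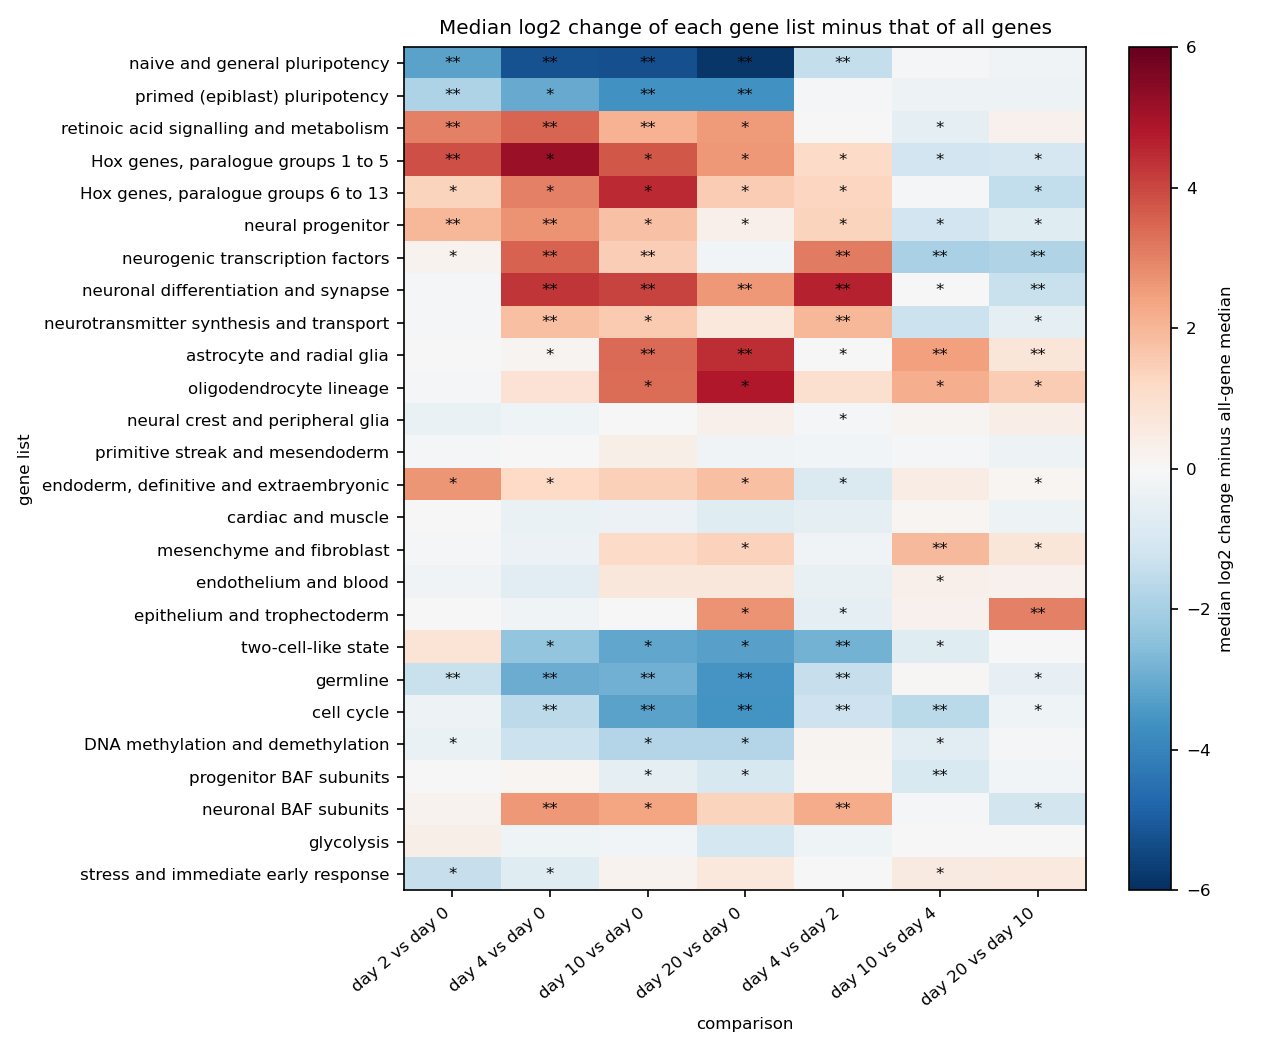
Median log2 change of each of 26 gene lists minus that of all genes (colour, -6 to 6) in 7 comparisons of days, with ** where limma's camera called the list with both the preset and the estimated correlation and * with the preset one only. The neuronal median is highest for day 4 against day 2 (4.60), that of pluripotency genes is lowest for day 20 against day 0 (-5.84), and that of epithelial genes is highest for day 20 against day 10 (3.0).

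Between days 2 and 4 neuronal genes rose, and genes of the 2-cell-like, germline and cell cycle lists fell. Nefm, a neurofilament subunit, rose from 2.81 ± 0.407 to 522 ± 17.1 FPKM (7.11 ± 0.10) and Gap43 from 3.18 ± 0.374 to 362 ± 5.84 (6.45 ± 0.18). Dcx rose from 0.54 ± 0.0608 to 133 ± 8.46 (6.45 ± 0.08) and Cntn2, an axonal adhesion protein, from 0.75 ± 0.145 to 142 ± 2.53 (6.36 ± 0.07). Stra8 fell from 608 ± 9.19 to 13.4 ± 0.324 FPKM (-5.41 ± 0.13). The gene models Gm8332, Gm4340 and Gm6803, which may share reads with near-identical copies, changed by -4.74 ± 0.13, -4.48 ± 0.17 and -4.36 ± 0.14. Tubb3 rose from 9.67 ± 0.306 to 688 ± 3.99 FPKM, from a level below that of day 0. Isl1, a factor of motor and sensory neurons, rose from 1.03 ± 0.193 to 69.7 ± 5.47 FPKM and Myt1 from 0.373 ± 0.0569 to 76 ± 5.63.

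All 35 neuronal genes rose in this step (median 4.60, adjusted p = 4.3e-05 with an estimated correlation), as did all 13 transmitter genes (adjusted p = 0.0004 with an estimated correlation). Neurogenic transcription factors rose in 24 of 29 cases and fell in 0 (adjusted p = 0.000403 with an estimated correlation). Neuronal BAF subunits rose in 5 of 6 (adjusted p = 0.0184 with an estimated correlation). In the retinoic acid list 10 of 23 measured members rose and 7 fell (camera adjusted p = 0.0616) and in the neural progenitor list 16 of 25 rose and 9 fell (camera adjusted p = 0.00242, adjusted p = 0.393 with an estimated correlation). Hox genes of groups 6 to 13 rose in 9 and fell in 3 of 14 cases (camera adjusted p = 0.00258, adjusted p = 0.27 with an estimated correlation). Hoxc6 rose from 1.41 ± 0.202 to 41.1 ± 0.535 FPKM, whereas the early gene Hoxb1 fell from 17.1 ± 1.01 to 1.95 ± 0.32. In the neural crest list 4 members rose and 4 fell of 10, and its median of -0.11 lay against the direction of the test (camera adjusted p = 0.0113, adjusted p = 0.538 with an estimated correlation). The largest rises in it were those of Ngfr (from 1.64 ± 0.127 to 98.6 ± 0.63 FPKM), Prph (from 2.95 ± 0.318 to 41.4 ± 1.64) and Ret (from 3.14 ± 0.403 to 24 ± 0.656), genes that neurons also express.

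Every member fell in the 2-cell-like list (12 genes, median -2.83, adjusted p = 0.0289 with an estimated correlation), Zscan4f from 86.8 ± 1.15 to 4.87 ± 0.206 FPKM. All 14 germline genes fell (adjusted p = 0.00242 with an estimated correlation), Dmrt1 from 13.3 ± 0.379 to 0.407 ± 0.123 FPKM, and all 25 cell cycle genes (adjusted p = 0.000323 with an estimated correlation), Mcm3 from 121 ± 7.88 to 38.1 ± 0.561. Pluripotency genes fell in 23 of 26 cases (adjusted p = 0.0004 with an estimated correlation), Dppa5a from 586 ± 31.7 to 38.6 ± 1.11 FPKM. Of endoderm genes 1 of 28 measured members rose and 18 fell (camera adjusted p = 0.00149, adjusted p = 0.296 with an estimated correlation), Apob from 28 ± 0.706 to 3.74 ± 0.244 FPKM. Of epithelial genes 0 of 17 measured members rose and 11 fell (camera adjusted p = 0.033, adjusted p = 0.223 with an estimated correlation), and Cldn6, a tight junction gene, fell from 212 ± 10.9 to 84.4 ± 2.63 FPKM.

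Calls numbered 10788 in this step, 5695 higher and 5093 lower at day 4, with 3203 at least 2-fold, 2019 up and 1184 down (limma). The all-gene median was 0.01 as deposited, -0.08 after quantile normalization and 0.22 rescaled to the same sum. In the same order 52.8%, 43.8% and 67.9% of calls were higher, and 63.0%, 52.5% and 77.2% of 2-fold calls. All 22 genes named were called (highest adjusted p = 1.3e-08), 22 of them with no overlap between libraries of the 2 days, for which many had been picked. In 24 of 26 lists the counts adjusted over the list alone were the same.

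From day 4 to day 10 glial and collagen genes rose and early neuronal regulators fell. Gfap rose from 0.030 ± 0.0361 to 185 ± 13.3 FPKM (7.49 ± 0.16) and Sparcl1 from 2.76 ± 0.288 to 367 ± 17.7 (6.62 ± 0.07). Gkn2 rose from 3.88 ± 0.544 to 424 ± 23.3 FPKM (6.45 ± 0.14). Crabp2 fell from 396 ± 16 to 5.82 ± 0.353 FPKM (-5.86 ± 0.10) and Isl1 from 69.7 ± 5.47 to 0.448 ± 0.169 (-5.62 ± 0.13). The transporter gene Slc10a4 fell from 80.3 ± 2.12 to 1.05 ± 0.0607 FPKM. The proneural genes Neurog1 and Neurod4 fell from 67 ± 3.08 to 1.06 ± 0.168 and from 32.9 ± 0.771 to 0.402 ± 0.0597 FPKM.

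In the astrocyte and radial glia list 15 of 19 measured members rose and 1 fell (median 2.48, adjusted p = 0.000412 with an estimated correlation), Aldh1l1 from 0.787 ± 0.0493 to 87.3 ± 3.47 FPKM. In the oligodendrocyte list 13 of 15 measured members rose and 0 fell (camera adjusted p = 1.13e-07, adjusted p = 0.15 with an estimated correlation), and the precursor gene Gpr17 rose from 0.37 ± 0.070 to 19.8 ± 2.16 FPKM. Mesenchyme genes rose in 23 of 24 cases and fell in 0 (median 1.97, adjusted p = 0.00638 with an estimated correlation). The collagen genes Col3a1, Col1a1 and Col1a2 rose from 0.163 ± 0.156 to 24.3 ± 3.19, from 0.167 ± 0.0493 to 13.8 ± 1.52 and from 1.57 ± 0.323 to 26.2 ± 1.75 FPKM. Among endothelium and blood genes 7 of 10 measured members rose and 2 fell (camera adjusted p = 0.0242, adjusted p = 0.132 with an estimated correlation), with Cdh5, the endothelial cadherin, at 9.95 ± 0.237 FPKM.

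Neurogenic transcription factors fell in 21 of 29 cases and rose in 7 (median -1.96, adjusted p = 0.00605 with an estimated correlation). The neuronal list went both ways, 13 up and 16 down of 35, and its median of 0.03 before the all-gene shift lay against the direction of the test (camera adjusted p = 0.0348, adjusted p = 0.55 with an estimated correlation). Nefm fell from 522 ± 17.1 to 43.4 ± 1.02 FPKM while Grin1, an NMDA receptor subunit, rose from 1.67 ± 0.127 to 24.6 ± 1.18. Transmitter genes did likewise, 6 up and 7 down of 13 (camera adjusted p = 0.0969). Slc18a3 fell from 75.1 ± 2.26 to 3.3 ± 0.259 FPKM. All 15 Hox genes of groups 1 to 5 fell (camera adjusted p = 2.29e-05, adjusted p = 0.0968 with an estimated correlation). All 25 cell cycle genes fell (median -1.61, adjusted p = 0.000145 with an estimated correlation), Mki67 from 36.1 ± 1.44 to 6.93 ± 0.501 FPKM. All 7 progenitor BAF subunits fell (adjusted p = 0.0289 with an estimated correlation), Smarcc1 from 95 ± 2.16 to 31.7 ± 1.11. In the stress list 13 of 19 measured members rose and 5 fell (camera adjusted p = 0.0169, adjusted p = 0.456 with an estimated correlation), with Fos rising from 3.44 ± 0.295 to 139 ± 2.09 and Egr1 from 3.78 ± 0.106 to 91 ± 1.37 FPKM.

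This step had 11038 calls, 6205 higher and 4833 lower at day 10, of which 2875 were at least 2-fold, 1962 up and 913 down (limma). Its all-gene median was 0.07, -0.05 after quantile normalization and 0.22 rescaled to the same sum. Over these scalings 56.2%, 46.5% and 67.0% of calls were higher, and 68.2%, 53.8% and 78.5% of 2-fold calls. All 21 genes named were called (highest adjusted p = 9.18e-10), 21 of them with no overlap between libraries of the 2 days, for which many had been picked. In 23 of 26 lists the counts adjusted over the list alone were the same.

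Between days 10 and 20 epithelial genes rose and neuronal genes fell. Tff1 rose from 5.66 ± 1.88 to 3274 ± 342 FPKM (8.99 ± 0.29) and Krt13, a keratin of stratified epithelium, from 1.98 ± 1.46 to 513 ± 119 (7.56 ± 0.26). Ly6d rose from 0.436 ± 0.194 to 229 ± 61.3 (7.28 ± 0.14). The gene models Gm8797 and Gm26602 changed by -5.08 ± 0.28 and -4.69 ± 0.11 and Pnoc, which encodes the neuropeptide precursor prepronociceptin, by -4.05 ± 0.07. Hoxb9 fell from 136 ± 3.96 to 7.99 ± 0.483 FPKM (-3.94 ± 0.09). Mbp rose from 185 ± 12.7 to 1645 ± 300.0 and Aqp4 from 2.63 ± 0.185 to 132 ± 9.93 FPKM. Mog, another myelin gene, rose from 1.88 ± 0.138 to 25 ± 5.97, with 16.1 in replicate 4 of day 20 against 27.2 to 29.1 in the other 3.

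In the epithelium list 16 of 17 measured members rose and 1 fell (median 3.0, adjusted p = 0.0229 with an estimated correlation). Krt5 rose from 0.736 ± 0.546 to 181 ± 27 and Krt14 from 0.268 ± 0.0887 to 32.1 ± 5.03 FPKM. Astrocyte and radial glia genes rose in 14 and fell in 5 of 19 cases (median 0.73, adjusted p = 0.019 with an estimated correlation), S100b from 5.01 ± 0.41 to 65.5 ± 4.97 FPKM. In the oligodendrocyte list 13 of 15 measured members rose and 1 fell (camera adjusted p = 0.000214, adjusted p = 0.175 with an estimated correlation). Neuronal genes fell in 31 of 35 cases (median -1.32, adjusted p = 0.00173 with an estimated correlation), Dcx from 51.7 ± 3.41 to 6.54 ± 0.545 and Ina from 139.9 ± 4.8 to 19.7 ± 0.745 FPKM. Neurogenic transcription factors fell in 26 of 29 (adjusted p = 0.000896 with an estimated correlation), Ebf3 from 31.6 ± 1.82 to 1.43 ± 0.291 FPKM. For neuronal BAF subunits 1 of 6 measured members rose and 5 fell (camera adjusted p = 0.0301, adjusted p = 0.0802 with an estimated correlation). Of endoderm genes 12 of 28 measured members rose and 10 fell (camera adjusted p = 0.0119, adjusted p = 0.672 with an estimated correlation), Hnf4a from 8.2 ± 0.952 to 56.5 ± 3.27 FPKM. Mesenchyme genes rose in 21 and fell in 2 of 24 cases (camera adjusted p = 0.0445, adjusted p = 0.0857 with an estimated correlation), Thy1 from 5.61 ± 0.63 to 38.1 ± 3.65 FPKM. Cell cycle genes fell in 18 and rose in 1 of 25 cases (camera adjusted p = 0.0345, adjusted p = 0.0726 with an estimated correlation). Hox genes of groups 6 to 13 fell in 10 of 14 (camera adjusted p = 2.26e-06, adjusted p = 0.0819 with an estimated correlation), and 1 of 12 members of the 2-cell-like list rose (camera adjusted p = 0.902).

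The count of calls was 11270, 5567 higher and 5703 lower at day 20, with 2840 at least 2-fold, 1894 up and 946 down (limma). Here the all-gene median was -0.02, -0.12 after quantile normalization and -0.18 rescaled to the same sum. The respective shares of higher calls were 49.4%, 40.8% and 37.4%. For 2-fold calls they were 66.7%, 53.8% (1699 up and 1459 down) and 52.6% (1826 up and 1646 down), so the excess of rises depended on the scaling. All 18 genes named were called (highest adjusted p = 1.34e-12), 18 of them with no overlap between libraries of the 2 days, for which many had been picked. In 24 of 26 lists the counts adjusted over the list alone were the same.

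Chromatin openness was given for 174059 non-overlapping regions of the mm9 genome, of median width 422 bp, 3107 of them on X and 68 on Y. Each day had 1 column of values, while the labels list 7, 6, 9, 4 and 6 libraries at days 0, 2, 4, 10 and 20. Which of these entered a column is not given in the sources used here. With 1 column per day the values have no error and no test was made. Which gene a region belongs to was not analysed here. Openness is the deposited signal, whose definition and normalization are not given in the sources used here, and the 5 columns share 1 maximum, 31.3. Differences are given as higher or lower openness, on log2 values with 0.1 added, where the higher day reached 1 and the days differed at least 2-fold. Of the steps, that from day 0 to day 2 had the lowest correlation of openness. The Spearman correlation across regions, which are not independent replicates, was 0.225 in it, against 0.726 between days 2 and 4, 0.425 between days 4 and 10, 0.497 between days 10 and 20 and 0.089 between days 0 and 20. Day 0 also correlated at only 0.05 with day 4 and 0.075 with day 10. With 1 pooled column per day, a difference of the day-0 column as a whole cannot be told apart from a change between days. Regions at least 2-fold above every other day numbered 16384 at day 0, 1002 at day 2, 1037 at day 4, 6150 at day 10 and 5752 at day 20, and 41537 regions (23.9%) varied less than 2-fold over all days.

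Between days 0 and 2, 24458 regions were higher and 24902 lower. From X 91952091 to 91952275 openness went from 0.037 at day 0 to 3.08 at day 2 and 0.41 at day 20. From 76899283 to 76900295 on chromosome 17 it went from 10.6 at day 0 to 0.341 at day 2 and 0.331 at day 20. Against day 0, day 4 had 28243 regions higher and 31027 lower, among them chromosome 3 from 144306092 to 144306957 (0.602 to 12.1) and chromosome 3 from 141511972 to 141512869 (17.6 to 0.471). Day 10 had 28316 higher and 31629 lower than day 0, such as chromosome 6 from 114444572 to 114444709 (0.011 to 3.1) and chromosome 10 from 97470847 to 97471659 (16.5 to 0.458). At day 20, 28819 regions were higher and 30863 lower than at day 0, with chromosome 11 from 51908019 to 51908308 going from 0.3 to 8.09 and chromosome 6 from 18174941 to 18175494 from 14.6 to 0.436.

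Day 4 differed from day 2 in fewer regions, 7294 higher and 4271 lower, led by chromosome 5 from 12365625 to 12366352 (0.238 to 4.46) and chromosome 2 from 83543471 to 83543901 (3.19 to 0.423). From day 4 to day 10, 18498 regions were higher and 19145 lower, and from day 10 to day 20, 17092 were higher and 16904 lower. The split depended on the fold minimum. At 1.5-fold day 4 had 18648 regions higher and 18276 lower than day 2, and at 4-fold 739 and 48. Against day 0 it had 50084 higher and 45999 lower at 1.5-fold and 4798 and 8407 at 4-fold, and the majority was also of higher regions at 1.5-fold and of lower ones at 4-fold for days 2, 10 and 20. A region of chromosome 18 from 56463018 to 56463238 stood at 14.3, 6.32, 7.54, 0.180 and 16.3 over the 5 days, low at day 10 alone. A region of chromosome 8 from 86280666 to 86280884 was open at day 10 alone (0.647, 0.190, 0.171, 8.98 and 0.141). The median log2 openness of X regions, relative to all regions, was -0.09, 0.39, 0.00, -0.71 and -0.83 at days 0, 2, 4, 10 and 20. That of the 68 Y regions was 1.83, 0.75, 1.01, 1.06 and 3.14.

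**Figure D3:**
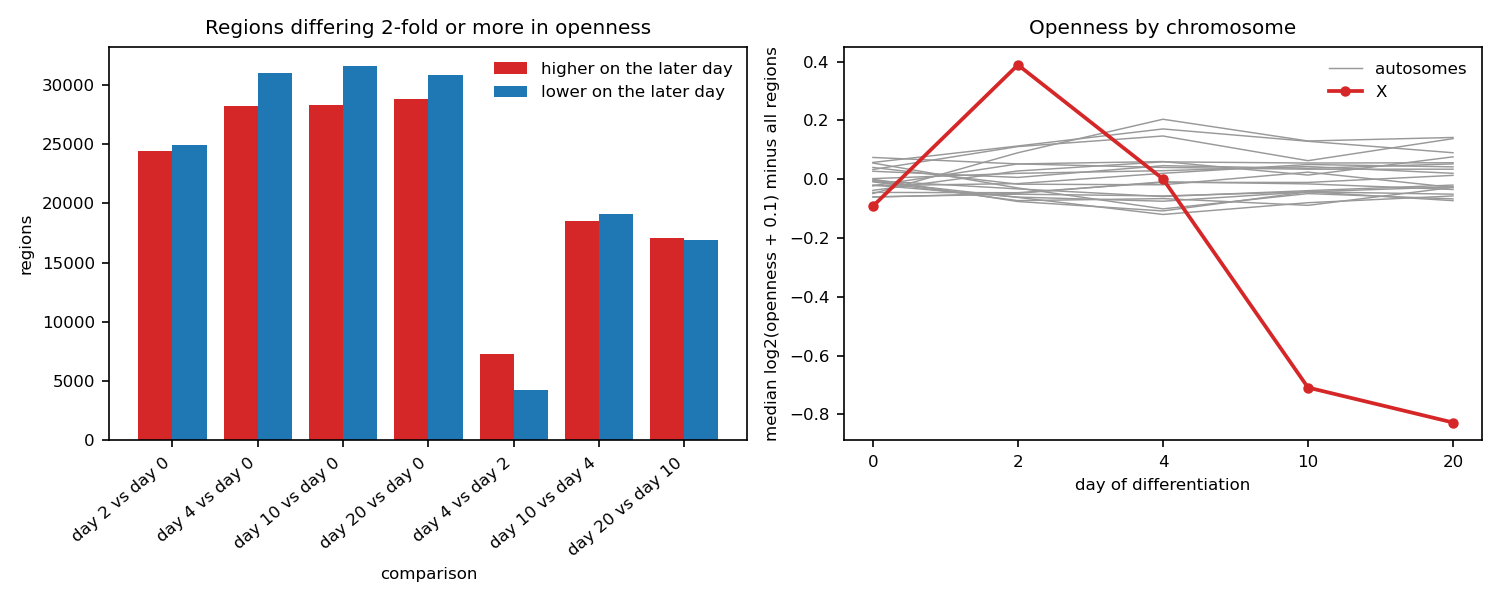
Left, regions differing at least 2-fold in openness in each comparison of days, higher (red) or lower (blue) on the later day, and right, the median log2 openness of each chromosome minus that of all regions, X in red and autosomes in grey, against the day with days evenly spaced. X lies at 0.39 at day 2 and -0.83 at day 20, while the largest autosome shift from day 0 to day 20 is 0.19.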

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

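The tests on day-0 replicate 6 were chosen after its values were seen, but their bounds were set before their results. Each named gene was searched for a library far from the others of its day: of 172 groups of 4 to 7 libraries, and 6 more of library sums and gene counts, 13 had a gap from the extreme library to its neighbour too large a part of the range (Dixon's critical value), where chance gives about 1 in 20.

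At day 0, replicate 6 lay above the rest for Fabp7 (0.93 FPKM against 0.07 to 0.33), Gfap (1.14 against 0.02 to 0.2) and Tff1 (2.74 against 0 to 0.76), all abundant at day 20. The excess over the other day-0 libraries was 0.0776%, 0.0739% and 0.0752% of the day-20 mean. If a trace of day-20 reads had entered this library, other genes of day 20 would show it too: of 30 more day-20-specific genes at 100 FPKM or more there and a median under 0.3 FPKM in the other day-0 libraries, replicate 6 was the highest day-0 library for 14 (46.7%, chance 14.3%), with a median excess of 0.0219% of the day-20 mean. The share lay between the bounds set for and against, so carry-over may be the source of these traces but was not settled, and low-level sampling noise limits the test. Noise from low depth would make replicate 6 the highest for genes of other days too, as it was for 0 of 7 day-4-specific genes and for the 1 day-10-specific gene chosen alike, numbers too small to settle this, and no biological explanation was tested.

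The other isolated libraries are given as values. At day 0 these were Actl6b in replicate 1 (0.17 FPKM against 0 to 0.03), Chat in replicate 4 (0.05 against 0 to 0.02), Neurog2 in replicate 5 (0.11 against 0 to 0.02) and Slc6a5 in replicate 4 (0.12 against 0.02 to 0.05). At day 10 they were Crabp2 in replicate 1 (6.43 against 5.5 to 5.75), Isl1 in replicate 1 (0.16 against 0.46 to 0.58) and Mog in replicate 5 (2.12 against 1.77 to 1.84). At day 20 they were Gm8797 in replicate 3 (0.67, listed at 0 in the other 3), Mog in replicate 4 (16.1 against 27.2 to 29.1) and Syp in replicate 1 (107 against 77.9 to 82.7).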

How the results depend on the processing

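The day-0 baselines, the rescaling of lists to the same sum, the alternatives for the F test and the chromosome settings were chosen after seeing the data. The 166 gene and comparison pairs named in the 7 comparisons of the report kept their direction and their call under every alternative run for them, pseudocounts, filters, scalings, variance models, thresholds, the block, both day-0 baselines and each library left out. Single genes of the closing section were not put through these alternatives. Many of the 166 pairs had been picked as large called changes, so their stability says little of other genes. Requiring 2-fold as well left 2999, 5423, 7063, 7771, 3203, 2875 and 2840 calls (days 2, 4, 10 and 20 against 0, then 4 against 2, 10 against 4 and 20 against 10), the stricter rule being the cause, and no other setting moved a total of calls by more than 1.5 times. Counts of 2-fold calls by direction moved more with the scaling, which shifts all genes: for day 20 against 10 the lower ones went from 946 to 1459 (quantile normalization) and 1646 (rescaled to the same sum), and for day 20 against 0 quantile normalization took 5256 higher to 3371 and 2515 lower to 3808. With 1 library left out calls ran from 10483 to 11164, 11970 to 12405, 13407 to 13593, 13451 to 13600, 10265 to 10842, 10455 to 11109 and 10978 to 11321 in the same order, from 14839 to 14875 for any difference among days and from 2619 to 2640 for day-specific genes (617 to 632, 111 to 119, 264 to 271, 223 to 238 and 1382 to 1408 by day). Day-specific genes numbered 10451 with no fold minimum (2654, 1118, 1440, 1777 and 3462 by day), 774 at 4-fold (177, 17, 59, 11 and 510) and 1468 with a pseudocount of 5 (376, 47, 167, 75 and 803), as a stricter fold or a larger pseudocount removes genes by construction. At a pseudocount of 0.1 they numbered 3283 (784, 164, 303, 379 and 1653 by day), as a smaller pseudocount enlarges the fold of low genes by construction. Whether this is the whole cause was not tested. Of the list and comparison pairs called, 46 of 104 were called with an estimated correlation and fry called 173, which by construction asks another question. Scaling, the block and the day-0 baselines turned 0 list calls around. Calls lost and gained were 0 and 3 with median-ratio rescaling, 4 and 8 with quantile normalization, 1 and 4 rescaled to the same sum, 2 and 11 against day-0 replicates 1 to 3 and 3 and 8 against replicates 4 to 7. For openness, a pseudocount of 0.5 gave 32162 (day 2 against 0), 5282 (4 against 2), 22711 (10 against 4) and 20335 (20 against 10) regions, and a minimum of 2 gave 31558 (2 against 0), 37404 (4 against 0) and 6219 (4 against 2). At 1.5-fold there were 85129, 96083, 97520, 97376, 36924, 71927 and 70036 regions and at 4-fold 9923, 13205, 12141, 12498, 787, 3352 and 3313, by construction. Count models and the comparison of openness with expression were not run, for want of counts and of an mm9 annotation, nor were openness settings that need a column per library.

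Replicate numbers as a block gave 10954, 12231, 13504, 13565, 10956, 11068 and 11392 calls, 14863 for any difference among days and 106 list pairs, 1 call lost and 3 gained, and changed no call of the named pairs, while day-specific genes, the families of the closing section and the sets of day-0 libraries were not run with it. Deviations of same-numbered libraries of different days correlated at -0.15 to 0.22 over 34 pairs, and 2 of 22 libraries correlated best with their own number, so the numbers were not taken as pairs.

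At most 100 splits of the same libraries were run per comparison, drawn at random beside the real one where more were possible. Only the real one called as many genes. In fits on the 2 days' libraries alone, the real count and the highest of the others were 10796 and 1 for day 2 against 0. They were 12177 and 148 for day 4, 13540 and 11163 for day 10 and 13330 and 0 for day 20. For day 10 against 4 (56 splits) they were 12058 and 0, and for day 20 against 10 they were 11624 and 8570. Random assignment of libraries to days was excluded in these. The splits say nothing of differences between cultures, as a day's libraries may be technical. For day 4 against 2 the counts were 11370 and 0, but 10 splits are too few for a share under 0.05. Over 100 regroupings of all libraries the values were 14872 and 3840 for any difference and 2630 and 1220 for day-specific genes. For list pairs with an estimated correlation they were 46 and 0. Random regrouping was excluded as the source of these counts, within the same limit. For list pairs with the preset correlation the values were 104 and 93, with a median of 78, so the real grouping gave the most but random grouping came close. Regrouped libraries keep their differences between days, so the 78 is not a count of false calls among the 104.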

Other observations

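The families of genes here were picked after their values were seen, among several times as many patterns of gene names looked at, so no p-value is given for them and their genes are counted as called over all genes, and the tests on chromosome X and on the dilution of day-0 genes were also chosen after the result was seen. Many genes of surface epithelia rose between days 10 and 20. Of stomach surface and mucous genes 18 of 20 measured members rose and 0 fell (median 4.36 relative to all genes), with Gkn1, a gastrokine, rising from 178 ± 13.4 to 905 ± 88 FPKM, Muc1, a membrane mucin, from 4.21 ± 0.466 to 121 ± 11.2 and Anxa10 from 0.18 ± 0.129 to 60.1 ± 4.54. In a family of small proline-rich and keratin genes 20 of 22 measured members rose and 1 fell (median 3.87). Of cilium axoneme genes 33 of 42 measured members rose and 2 fell, and Foxj1, a regulator of motile cilia, rose from 8.09 ± 0.731 to 36.2 ± 4.11 FPKM. Immune genes also rose in the same step. Interferon-response genes rose in 38 of 38 cases, Isg15 from 3.84 ± 0.584 to 85.4 ± 24.3 FPKM and Irf7 from 2.52 ± 0.328 to 40.03 ± 8.66. Complement genes rose in 10 of 13 cases, C3 from 1.42 ± 0.216 to 73.5 ± 4.61 FPKM. Genes of MHC class I antigen presentation rose in 15 of 17 cases, H2-K1 from 122 ± 7.4 to 359.9 ± 16.2 FPKM. The directions of these families held under all 3 other scalings.

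Other families picked in this way held adhesion, receptor and channel genes. All 52 measured clustered protocadherins, adhesion proteins that differ from neuron to neuron, were higher at day 10 than at day 0, Pcdhb11 rising from 0.00286 ± 0.00488 to 9.3 ± 0.27 FPKM, and 47 of them fell by day 20, though their exons are alike enough for reads to be shared. Between days 0 and 10, of glutamate, GABA and glycine receptor subunits 38 of 39 measured members rose and 0 fell (median 2.25), Gria2 from 0.0143 ± 0.023 to 21.8 ± 0.688 FPKM, of potassium channel subunits 56 of 64 measured members rose and 2 fell, Kcnj10, a channel of astrocytes, from 0.0786 ± 0.0508 to 17.5 ± 0.461, and of sodium channel subunits 8 of 8 measured members rose and 0 fell. Over the same days cytoplasmic ribosomal protein genes fell in 78 of 80 cases (median -1.71), but the median was only -0.24 after quantile normalization, so its size depended on the scaling. For replication-dependent histone genes, most of whose RNA lacks a polyA tail and which share reads, 5 of 49 measured members rose and 37 fell.

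Day-0 replicates 1 to 3 differed from replicates 4 to 7 in 3840 genes. In the endoderm list 18 of 28 members were higher and 1 lower in replicates 4 to 7, with a median of 0.57. Lower depth is argued against, since 47.7% of genes at 50 FPKM or more were called against 13.4% under 5 FPKM. Endoderm-type cells in replicates 4 to 7 may account for part of the difference: in another endoderm list, drawn up after the first shift was seen and sharing no gene with it (it holds Rbp4 and Cyp26a1 of the retinoic acid list), 15 of 22 members (68.2%) were called higher and 1 lower. They do not account for the 16 genes called at least 2-fold lower there, as dilution lowers all other genes alike and the pluripotency median was only -0.10. That median hides differences both ways: 9 of 26 pluripotency genes were called higher and 12 lower in replicates 4 to 7. Of DNA methylation genes 0 of 11 were called higher and 5 lower. A difference in handling or time stays open, as untested.

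X openness relative to all regions went from 0.39 at day 2 to -0.83 at day 20, while that of the 68 Y regions moved more, by -1.08 from day 0 to day 2 and 1.31 from day 0 to day 20. Against autosomal regions matched on day-0 openness and width, X lay at -0.518 on the log2 scale at day 20, so a different start is argued against. The largest autosome shift was 0.19 and that of X -0.73. These shifts are relative to all regions of a column, so a factor on the whole column largely drops out and they cannot test its scaling. Fewer X copies in the cultures were not settled by RNA as an explanation. The loss of an X known from female stem cell lines does not apply to R1, a male line. In male cells fewer copies would mean no X at all. X-linked RNA changed by 0.01 (95% bootstrap interval -0.15 to 0.22) at day 10 and -0.14 (-0.361 to 0.04) at day 20 relative to autosomal genes, over 555 X genes. The interval at day 10 lies above the -0.35 set for this explanation after a first value had been seen. This argues against fewer X copies at day 10 in the cultures the RNA came from. The lower bound at day 20, -0.361, reaches -0.35, so the RNA values alone do not decide on fewer copies there. Nothing says that both assays used the same cultures.

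Of the 4 consecutive steps, that from day 0 to day 2 had the lowest Spearman correlation of openness across regions, 0.228 without X and Y, against 0.726, 0.423 and 0.491 for the later steps. Over regions at 2 or more on any day it was 0.220, against 0.759, 0.342 and 0.417. As day 0 is 1 pooled column, a difference of that column as a whole cannot be told apart from a change in this step.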
